A study of Mus musculus with 2 samples.

How the data were processed

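Whole-genome bisulfite libraries of 2 samples were compared, 1 from Ngn3 heterozygous and 1 from Ngn3 null cells of the mouse pancreas at E14.5. Bisulfite treatment turns unmethylated cytosine into uracil, so that a cytosine read after it marks methylation (or hydroxymethylation, which this method does not separate). Per the labels' protocols, eGFP-positive cells of over 95% viability were sorted and lysed directly, and 75 ng of genomic DNA was tagmented with Tn5 transposase, gap-repaired, bisulfite-converted and amplified by 12 PCR cycles. Paired-end reads of 150 bp were sequenced, about 400000000 per library. The strain was mixed and mostly ICR. PCR duplicates, uneven Tn5 insertion and incomplete conversion can all change a methylation call; how they were handled is not given in the sources used here. Per the submitters' processing notes, Trim Galore was used, and the genome builds named were mm10 and GRCm38. The aligner, the methylation and region callers, their thresholds, the coverage minimum and the rule for the nearest gene are not given in the sources used here.

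The authors deposited 1 table, analysed here, which holds gene names and no measured quantity, so its 9 columns have no unit. Per the file headers, the first column names the nearest genes to regions of lower methylation in null cells, and the second starts the names for higher methylation. The 7 columns after it have no header. They were read as the same list because each carries on the alphabetical order of the column before. Names occur once per list, so counts are of genes, never of regions.

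Names were matched without regard to case to the symbols, NCBI gene IDs and, where unique, older symbols of 49997 genes of the RefSeq annotation of GRCm38.p6, the build family that the labels name. Of the lower list, 406 of 429 names matched (340 by current symbol, 22 by gene ID and 44 by older symbol). Of the higher list, 3145 of 3230 matched (3072 by current symbol and 73 by older symbol). Names in capitals numbered 225 and 2402. Unmatched were 23 and 85 names, among them 13 and 75 UCSC transcript IDs. Another 3 were the numbers 43164, 43352 and 43358, which as spreadsheet day serials fall on day 5 of month 3, day 9 of month 9 and day 15 of month 9 of 2018. No name in either list began with March or Sep and a digit. Matching by name alone gave 116 names common to both lists, and matching to genes gave 130, since some genes were given by ID or older symbol in 1 list and by current symbol in the other. Coordinates are those of the annotated gene in GRCm38.p6, 1-based, and not those of a methylated region.

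The design assumed that the table might hold levels, counts or positions. It holds none, so the planned methylation levels, region lengths, locations relative to genes and distances between regions were not computed. The share of names per direction has an exact Clopper-Pearson 95% interval. For each of 18 gene lists (610 distinct genes) fixed before the data were examined, the number of members in each list was set against 10000 random sets drawn without replacement from 21887 protein-coding genes on the autosomes, X and Y, matched on 10 bins of gene length. Counts in parentheses or sentences give all list members, and random sets only protein-coding ones. A count was described as above or below random sets at 2.5% on each side. Genes per chromosome were set against chromosome length, with the end of the last annotated gene standing in for length, and have exact Poisson intervals. Other splits of the samples, replicate errors and left-out replicates do not exist with 1 library per genotype.

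The rule for named genes, fixed before the data were examined, takes up to 30 members of the fixed lists, with some lists first, and Neurog3 in any case. It ranked the remaining lists by size of the difference, which the table does not hold, so they were taken in their listed order. That order, and the use of the rule once per direction, were not part of the rule as fixed. Some genes that the rule takes are not reported here. Further members named as examples of their list, and the members of symbol families, were chosen after the table had been seen. Alternatives planned before were random sets without length matching for the gene lists and autosomes only for the share per direction. Those chosen after seeing the data were autosomes only for the gene lists, matching on territory (a gene plus the gap up to the midpoint with each neighbouring protein-coding gene, 10 bins), 100 length bins, all gene classes, current symbols only, predicted and chemosensory genes left out, other expectations per chromosome, and sets of other transcription factor genes as the reference for the endocrine and progenitor factors. Also chosen after were the share per direction among matched names, protein-coding genes and genes named in 1 list only, the overlap of both lists against unmatched and territory-matched sets, and the number of imprinted genes shared given their counts in both lists.

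The random-set method was tested on simulated tables of the same 21887 genes, made with the rates of each length decile. Lists of 40 genes enriched by 3-fold were found above random sets in 95.5% of 200 cases at the higher list's rate and in 19.5% at the lower list's rate. Lists that differed only by holding longer genes were found above in 2.0% and 1.0%, and without length matching in 27.5% and 4.5%. The simulated rates were equal within each decile and the matching used the same deciles, so a low share was built in. Length effects left inside a decile were not tested by it. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.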

Results

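DNA methylation was compared by whole-genome bisulfite sequencing between 2 libraries made from cells of the E14.5 mouse pancreas that had been sorted for an eGFP reporter carried at the Ngn3 locus. Ngn3, whose current symbol is Neurog3, is the basic helix-loop-helix transcription factor that starts endocrine differentiation in the pancreas. One library came from heterozygous embryos, in which 1 allele carries the reporter, and the other from embryos with the reporter on both alleles, termed null here. The comparison asks which parts of the methylome of these sorted cells differ when Neurog3 is missing. The labels call the heterozygous cells islet progenitors and the null cells endocrine progenitors. A direct effect of genotype therefore cannot be told apart from a difference in the stage or make-up of the sorted cells. Each genotype had 1 library and no replicate, so no difference has a replicate check and no p-value is given. The labels state about 400000000 reads per library. The coverage behind each region is unknown, because the table analysed holds only the names of the genes nearest to differentially methylated regions, each name once, in a list for regions with lower methylation in the null library (the lower list) and a list for regions with higher methylation in it (the higher list). It gives no methylation level, region position or number of regions per gene.

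Most named genes lay nearest to regions that were more methylated without Neurog3. The higher list held 3230 names and the lower list 429, a ratio of 7.53. The higher list therefore made up 88.3% of the 3659 entries (exact Clopper-Pearson 95% interval 87.2 to 89.3%, which covers counting error only). On autosomes alone the share was 88.9%. Among protein-coding genes the lists held 2645 and 331. The higher list also matched 362 long noncoding RNA genes and 110 microRNA genes, and the lower list 54 and 12. Neurog3 itself (chromosome 10, 62133090 to 62134763 in GRCm38) was in neither list, which does not test the genotype because the lists report methylation near a gene and not its expression.

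Long genes were named far more often than short ones. Of the genes in the longest length decile, 38.4% were in the higher list and 4.89% in the lower list, against 1.92% and 0.457% in the shortest decile. The median length was 55.2 kb for protein-coding genes of the higher list, 51.0 kb for those of the lower list and 17.2 kb for all 21887 protein-coding genes. Each gene list below was therefore set against 10000 random sets of protein-coding genes of the same size and the same length deciles. A list is described as above random sets where at most 2.5% of these held as many named genes, a description of these libraries and not a test between genotypes. Of the 36 pairs of list and direction, 7 were above random sets and 0 below, against at most 1.8 outside on either side by chance. That chance figure takes each list as a random draw of genes. In the higher list every fixed list except the Hox genes lay above the random mean. The 7 are therefore not shown to stand out from chosen lists in general.

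**Figure D1:**
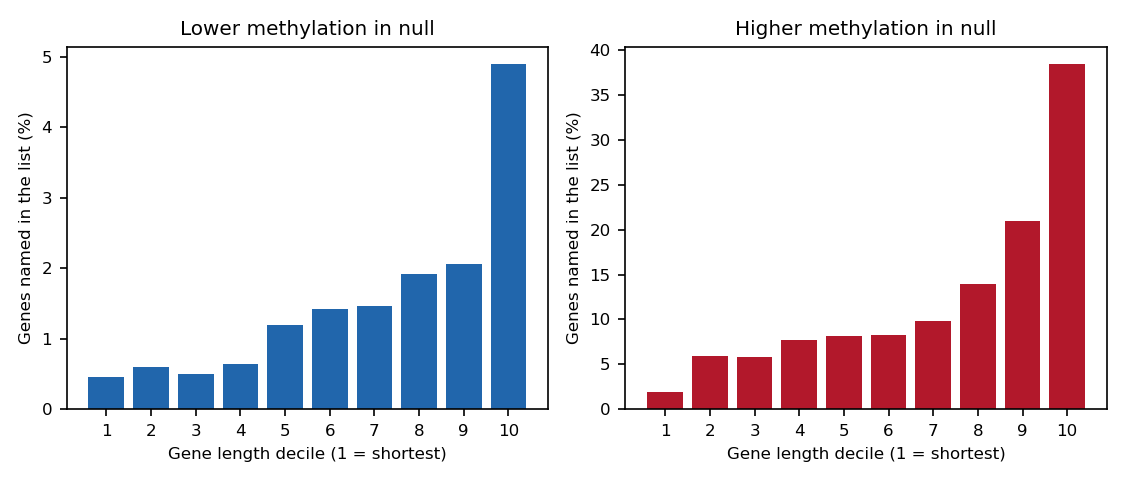
Percentage of protein-coding genes named in the lower list (left) and the higher list (right) in each decile of gene length, from the shortest (1) to the longest (10). Bars go from 0.457% to 4.89% in the lower list and from 1.92% to 38.4% in the higher list.

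Transcription factors of the endocrine lineage were frequent in the higher list. Of the 38 fixed genes, 15 were named there, against a median of 5 and a middle 95% of 1 to 9 in random sets, and 0 of 10000 random sets held as many. They included Pax4 (chromosome 6, 28442334 to 28449340) and Nkx6-1 (chromosome 5, 101659184 to 101664711), regulators of the beta cell lineage. Insm1 (chromosome 2, 146221997 to 146225020), a zinc finger factor of endocrine differentiation, was also there, as were Myt1, St18, Rfx3, Mnx1, Irx1, Irx3, Isl2, Tox3 and Glis3. Only Glis3, which lies across 421 kb of chromosome 19, was also in the lower list, against a random median of 0. Neurod1, Pax6, Nkx2-2, Isl1, Rfx6 and Fev, further endocrine regulators on the same list, were named in neither direction. Other transcription factor genes, gathered by symbol family after the table had been seen, were also above random sets, with 115 of 513 in the higher list against a median of 70 and a middle 95% of 56 to 85. In the lower list they had 16, above length-matched sets (3 to 14) and within sets matched on the span of genome around each gene (4 to 16). Against sets of 38 such genes, matched on that span more coarsely, in 4 bins instead of 10, the endocrine count of 15 lay within the middle 95% of 5 to 15.

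Genes of hormone production and secretion were above random sets in the higher list by a smaller margin. Of 48 such genes, 14 were named there, against a median of 8 and a middle 95% of 3 to 13 in random sets, and 0 in the lower list. They were Ins1, an insulin gene (chromosome 19, 52264297 to 52265015); Abcc8, the sulfonylurea receptor subunit of the beta cell potassium channel (chromosome 7, 46104523 to 46180039); the prohormone-processing genes Cpe and Pam; the voltage-gated calcium channel genes Cacna1a, Cacna1c and Cacna1d; and Ptprn2, Scgn, Rab3c, Rab27a, Syt7, Rimbp2 and Cadps, which serve vesicles and exocytosis. Ins2, Gcg and Sst were named in neither list. With random sets matched in 100 length bins, the count was no longer above them (middle 95% of 4 to 14).

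Regulators of the pancreatic progenitor were the third such group. Of 28 genes, 13 were in the higher list, against a median of 4 and a middle 95% of 1 to 7, and 0 of 10000 random sets held as many. The group included Hnf4a, a nuclear receptor gene, together with Onecut2, Gata6, Prox1, Nr5a2, Rbpj, Hes1, Etv5 and Tead1, and it shared Nkx6-1 and Mnx1 with the endocrine list. Nr5a2 and Tead1 were in the lower list as well, which is 2 of 28 against a random middle 95% of 0 to 2. Pdx1, Ptf1a, Sox9 and Foxa2 were in neither list. Of the 22 members used in the comparison with other transcription factor genes, 11 were in the higher list, against a middle 95% of 3 to 11 in sets of other such factors.

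**Figure D2:**
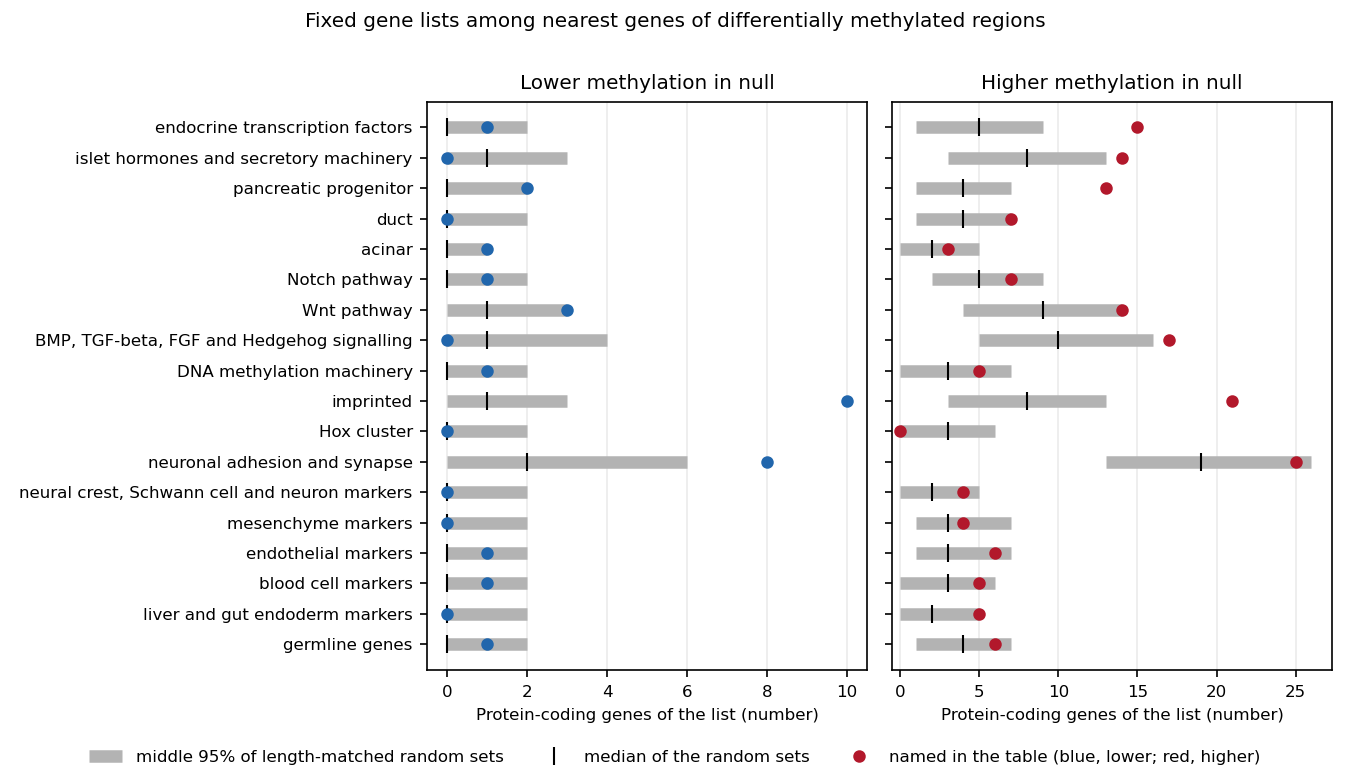
Number of protein-coding genes of each fixed list named in the lower list (left, blue) and the higher list (right, red), with grey bars for the middle 95% of 10000 length-matched random sets and black ticks for their medians. Outside the bars lie the imprinted (10) and neuronal (8) lists on the left, and the imprinted (21), BMP to Hedgehog (17), endocrine (15), islet (14) and progenitor (13) lists on the right.

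Signalling genes were less distinct. Of 55 genes of BMP, TGF-beta, FGF and Hedgehog signalling, 17 were in the higher list (random median 10, middle 95% 5 to 16) and 0 in the lower list. Members included the ligand genes Bmp4, Bmp7, Shh and Inhbb, the receptor genes Fgfr2, Fgfr3, Tgfbr2 and Ptch1, and the antagonist gene Nog. This count was no longer above random sets once these were matched on the span of genome around each gene (middle 95% 6 to 17). The Wnt pathway had 14 of 56 genes in the higher list and 3 in the lower list (Wnt11, Fzd6 and Lrp6), both within the random range. The Notch pathway had 7 of 36 in the higher list, among them Notch2, Hey1, Maml2 and Maml3, against a middle 95% of 2 to 9. Of 25 genes that write, read or remove DNA methylation, 5 were in the higher list (Tet2, Mbd2, Zbtb38, Gadd45b and Gadd45g) and 1 in the lower list (Gadd45a), also within the random range. Dnmt1, Dnmt3a and Uhrf1 were in neither.

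Imprinted genes, which carry methylation on the allele of 1 parent at their control regions, were above random sets in both directions. Of 53 such genes, 16 were in the lower list and 24 in the higher list. Counting the 45 protein-coding ones, 10 were in the lower list against a random median of 1 and a middle 95% of 0 to 3, and 21 in the higher list against a median of 8 and a middle 95% of 3 to 13. In each direction 0 of 10000 random sets held as many. The lower list named H19 (chromosome 7, 142575530 to 142578146), Kcnq1ot1 (chromosome 7, 143213111 to 143296547), Meg3 (chromosome 12, 109540996 to 109571729), Peg10, Magel2 and Slc22a18, none of which was in the higher list. Airn (chromosome 17, 12741311 to 12859884), Mest, Grb10, Gnas, its antisense gene Nespas (current symbol Gnasas1), Kcnq1, Dlk1, Peg13, Trappc9 and Slc38a4 (chromosome 15, 96994816 to 97055956) were in both. Igf2, Igf2r, Cdkn1c, Nnat, Sgce, Usp29, Rasgrf1, Mcts2 and Nap1l5 were among those in the higher list alone. Overlapping pairs such as Peg13 within Trappc9, Kcnq1ot1 within Kcnq1 and Gnas with its antisense gene cannot be told apart by nearest gene, so members of a pair are not independent. Protein-coding members also lie close together, such as Kcnq1 and Slc22a18 on chromosome 7. Random sets drawn gene by gene do not allow for this. Among the 24 named protein-coding imprinted genes, 10 were in the lower list, against a median of 3 and a middle 95% of 0 to 6 among random named genes of like length, where 3 of 10000 random sets held as many.

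Large neuronal adhesion and synapse genes were above length-matched random sets in the lower list. Of 52 such genes 8 were named there, among them Grm5, Ptprt, Lsamp, Ntm and Rbfox1, against a median of 2 and a middle 95% of 0 to 6. Lsamp, Ntm and Rbfox1 were also in the higher list, which held 25 of the 52, within the random middle 95% of 13 to 26. Genes such as Lsamp (2197 kb) lie far above the median of the longest decile (185 kb). With 100 length bins the lower count fell within the middle 95% of random sets (1 to 8).

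Markers of other cell types that the sort could hold, and of the alternative pancreatic fates, lay within the random range in both directions. In the higher list these were 7 of 25 duct genes, 3 of 28 acinar genes, 4 of 27 mesenchyme genes, 6 of 20 endothelial genes, 5 of 27 blood cell genes, 4 of 21 neural crest, Schwann cell and neuron genes, and 5 of 21 liver and gut endoderm genes. Each of these lists lay above the random mean there, from 1.18 times it for mesenchyme to 2.27 times for liver and gut genes. The islet list, described as above random sets, was at 1.80. An excess of like size in these small lists is therefore not excluded. The lower list held Nr5a2 of the acinar list, Kdr of the endothelial list and Lcp1 of the blood cell list, and 0 duct, mesenchyme, neural crest or liver and gut genes. Germline genes had 6 of 26 in the higher list and 1, Taf7l, in the lower list, within the random range. None of the 39 Hox genes was in either list. Random sets matched on length had a median of 3 in the higher list, and 608 of the 10000 also had 0. At the lower list's rate the middle 95% of random sets was 0 to 2 or narrower for these lists, so a moderate excess was not detectable there.

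Genes near regions of both kinds were more common than random sets gave. After names were matched to genes, 130 genes were in both lists, which is 32.0% of the lower list's 406 and 4.13% of the higher list's 3145. Of the protein-coding genes, 110 were shared, against a median of 67 and a middle 95% of 54 to 81 in length-matched random sets, and a mean of 40.1 in sets without length matching. Glis3, Nr5a2, Tead1, Dlk1 and Lrp6 were among them. The shared protein-coding genes had a median length of 114 kb and an upper quartile of 295 kb, against a median of 185 kb in the longest decile. Random sets with finer length bins were not run for the shared genes. Length effects inside a decile are therefore not allowed for, and the share of the excess that gene length accounts for is not settled. Both lists come from the same pair of libraries, and a gene with several regions can be nearest to some of each kind.

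X-linked genes were scarce in the higher list. It named 26 protein-coding genes of the X chromosome, which is 0.157 of the number expected from chromosome length (exact Poisson 95% interval 0.102 to 0.230, counting error only). The lower list named 12, a ratio of 0.578 (0.299 to 1.01). Against an expectation from gene number and length deciles the ratios were 0.226 (0.148 to 0.331) and 0.842 (0.435 to 1.47). The lower list held 31.6% of the 38 X-linked entries (exact interval 17.5 to 48.7%) and 10.8% of the 2933 autosomal entries (9.71 to 12.0%). The Y chromosome was about as scarce in the higher list against gene number and length deciles, at 0.236 (0.0486 to 0.688) with Kdm5d, Zfy1 and Zfy2. The lower list named Uty and Eif2s3y, at 1.01 (0.123 to 3.66). All named Y genes lay between positions 725207 and 2170409, and how many other Y genes could be assayed is not known. The most overrepresented autosome in the higher list by chromosome length was chromosome 11, with 204 genes and a ratio of 1.72. Its ratio was 1.19 (1.03 to 1.36) against gene number and length deciles. Of the 19 autosomes only chromosome 11 had such an interval that excluded 1, and 1 among 19 can arise by chance. The labels do not give the sex of the embryos.

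**Figure D3:**
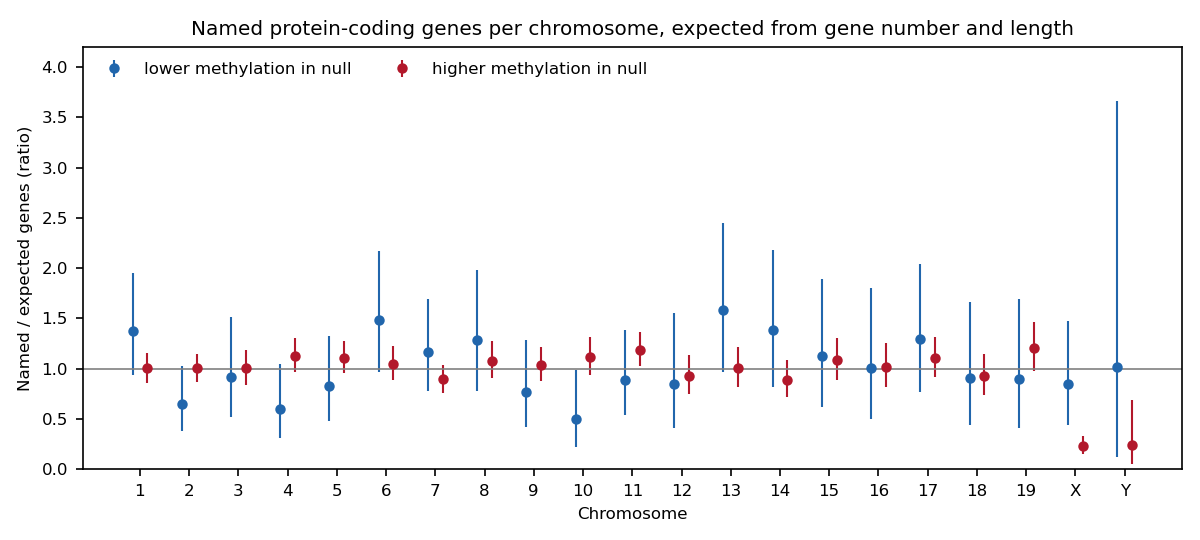
Ratio of named to expected protein-coding genes per chromosome for the lower list (blue) and the higher list (red), with the expectation from gene number and length deciles and exact Poisson 95% intervals as bars. In the higher list the X chromosome lies at 0.226, the lower list's X ratio of 0.842 has an interval that includes 1, and the Y points rest on 2 and 3 genes.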

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

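Of 252 values of the 36 list results under 7 alternatives, 244 kept their place above, within or below the random range. Another 3 lost and 5 gained a place outside it, and 0 reversed. Ratios that crossed 1 while within the range counted as kept, such as mesenchyme genes in the higher list (1.18, and 0.816 matched on territory). The endocrine, progenitor and both imprinted results stayed above random sets under all 7. Against random sets of other transcription factor genes, a further comparison, the endocrine factors were at 1.52 and the progenitor factors at 1.68, both within the range. As ratios to the random mean in the higher list, matching on 100 length bins gave 1.58 for islet hormones and secretory machinery, and matching on territory gave 1.54 for BMP, TGF-beta, FGF and Hedgehog signalling, both then within the random range. In the lower list, neuronal adhesion and synapse genes fell to 1.84 with 100 length bins, within the range; the random mean rose because the bins hold genes of more similar length. Without length matching, 4 results of the higher list left the range: duct at 2.34, Wnt at 2.06 and neuronal genes at 3.97 above it, and Hox at 0 below it. Neuronal genes in the higher list were also above territory-matched sets, at 1.67. Leaving out genes named in both lists moved the share of the higher list to 91.6%, by construction since this takes the same number from each. Chromosome 11 in the higher list moved from 1.72 times the number expected from chromosome length to 1.05 against gene number and 1.19 against gene number and length. Choices of methylation difference, deposited p-values, CpG number, coverage, merging, distance to the TSS, promoter windows, counting by region and CpG content per chromosome were not varied (not run), since they need levels, positions or a genome sequence not used here. No paired analysis was possible because each genotype has 1 library. The lower list is small: at its rate, 19.5% of simulated lists with a 3-fold excess were found.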

Other observations

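Of the tests of explanations below, the one against other transcription factor genes was set before its result was seen. The others were set with their values in view, some of them on results planned beforehand. Chemosensory receptor genes were rare in the higher list. Of 1110 olfactory receptor genes 5 were named there, against a median of 63 in random sets matched on territory and 29 in sets matched on length. Of 355 vomeronasal receptor genes 3 were named, against 37 and 18. Among 326 pairs of symbol family and direction, these 2 were below all but 0.1% of random sets by both matchings and 0 were above, with at most 0.326 expected each way by chance. In the lower list 4 olfactory and 2 vomeronasal receptor genes were named, within the random range.

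Families of leukocyte receptors and regulators had 9 of 266 genes in the lower list. They were chosen because such names had been noticed there, so this count is not set against random sets. The 9 included the interferon regulatory factor genes Irf4 and Irf8, the Fc receptor gene Fcgr1, the Toll-like receptor gene Tlr8 and Treml2. In the higher list the families had 21 genes, within the random range. The blood cell list fixed beforehand had 1 gene in the lower list, Lcp1, against a middle 95% of 0 to 2.

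Imprinted loci were named in both directions. Of 24 imprinting loci, each counted by 1 or 2 genes set for it, 17 had such a gene in the table: 10 in both lists, 6 in the higher list only and 1 in the lower list only. The antisense gene of Peg3 (Peg3os, listed as Apeg3) and Dio3os, which neither the fixed list nor this tally holds, were in the lower list, so the locus of Peg3 and Usp29, tallied as higher only, also had a neighbouring gene in the lower list. Large genes and gene gaps, as far as 10 territory bins allow for them, do not account for this. Imprinted genes stayed at 9.80 times the territory-matched mean in the lower list. A loss of imprint methylation in null cells alone is argued against as the whole account of both lists by the ratio of 2.67 in the higher list. Region positions are unknown, so the more methylated regions need not lie at imprint control regions, and a loss there is not excluded. Whether intermediately methylated regions vary more between any 2 libraries stays open as a hypothesis, as does a real shift in both directions. With 10 and 21 of 45 protein-coding imprinted genes named, 4.67 would be shared by chance and 7 were, a number reached in 9.37% of random placements, and levels would be needed to separate these.

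X-linked genes were scarce in the higher list and not clearly so in the lower list. The Y chromosome, with few named genes, had a ratio of 0.236 in the higher list, but how many Y genes could be assayed is not known. Fewer or shorter genes on the X do not account for the X-linked scarcity, since the ratio in the higher list was 0.226 after both were allowed for. Less power on the X in both directions alike is argued against as the whole account: the lower list's ratio of 0.842 has an interval (0.435 to 1.47) that does not overlap that of the higher list (0.148 to 0.331). Pools with different shares of male and female embryos may tilt X-linked entries to the lower list, where 31.6% of them lay against 10.8% of autosomal ones. This cannot be told apart from an effect of genotype, because the labels give no sex and each genotype is 1 library.

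Endocrine and progenitor regulators were frequent in the higher list, and matching on territory lowered the excess without removing it. The endocrine list went from 3.04 times the length-matched mean to 2.03 times the territory-matched mean. The progenitor list went from 3.34 to 2.45, and both lists stayed above random sets. Spans still differ within a territory bin and finer territory matching was not run. The share that large genes and gene gaps account for is therefore not settled. Transcription factor genes of any lineage may account for much of the excess. Of 513 other such genes 22.4% were in the higher list, 1.44 times the territory-matched mean. Of random sets of 38 of them, matched on territory in 4 bins, 2.95% held as many as the endocrine list's 15. This meets, by a small margin, the mark of at least 2.5% set beforehand for this explanation. A further excess at endocrine genes in the absence of Neurog3 stays open as a hypothesis, which levels at their enhancers in replicate libraries would test.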
